A study of Arabidopsis thaliana with 18 samples.

How the data were processed

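Gene expression was measured on 18 one-colour Affymetrix arrays, each hybridised with biotin-labelled RNA from *Arabidopsis thaliana* rosette leaves. Each sample came from a pool of at least 250 plants. There were 2 genotypes, the wild type Col-0 (WT) and the *stn7* knockout line, which lacks a chloroplast thylakoid protein kinase. Plants grew for 20 days in white light of 35 µE at 22 °C and 60% humidity, then for 3 days in light that favours photosystem I (PSI light). They were harvested at 0 min, still in PSI light, or 30 min or 60 min after a shift to light that favours photosystem II (PSII light). Each of the 6 groups had 3 biological replicates. The label was made with a kit primed on poly(A) tails, a step that represents organelle transcripts poorly.

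The values are on the log2 scale as deposited, and the processing notes of the authors name GCOS, Affymetrix Expression Console 1.1 and RMA (background correction, quantile normalization and summary per probe set). The settings of RMA and the probe set definition file are not given in the sources used here. The table held 22810 probe sets. The 64 control probe sets were removed, so that 22746 were tested, with no filter on signal and no further scaling. The values ran from 2.53 to 14.02 and the array medians from 6.1 to 6.31. The number of arrays limits the precision, and dim probe sets lie near the background.

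The gene table supplied for these probes gave 1 gene for 13513 probe sets (59.4%) and several genes for 503. It did not list the other 8730. Of the probe sets with 1 gene, 13436 matched an entry of the RefSeq annotation (assembly TAIR10.1), and 88.3% carried only a locus name. Probe sets without an entry were tested and counted but were given no gene name. No probe set carried the locus of STN7 in this annotation, so the STN7 transcript is not analysed here.

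A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings). The moderated test had 17.8 degrees of freedom, of which 5.8 came from the prior. The test was two-sided, and p was adjusted by Benjamini-Hochberg over the 22746 probe sets within each of 12 comparisons. A probe set counted as changed at an adjusted p under 0.05. The comparisons were each pair of times within a genotype, *stn7* against WT at each time, *stn7* against WT as the mean over the 3 times, and the genotype difference in the 30 min and 60 min responses (the change in *stn7* minus the change in WT). Python 3.11.15 with pandas 2.3.3 read the tables, and matplotlib 3.10.9 drew the plots.

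The groups, comparisons, tests, threshold, gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, the 10 largest rises and the 10 largest falls among probe sets with 1 gene that passed the threshold and whose 3 arrays of each group did not overlap. No such condition on overlap was set for the genotype differences in response or for the mean over times. Members of the gene lists were named where they passed the threshold, or up to 4 with the smallest p. STN7 was to be named in every comparison, which the annotation did not permit. Anything else is said to have been chosen after its values were seen.

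In all, 29 gene lists were fixed. Of their 335 genes outside the organelle genomes, 44 had a named probe set, and 12 lists had at least 3 measured members and were tested as sets. These were thylakoid kinases and phosphatases, light-harvesting antenna, photosystem II subunits, Calvin-Benson cycle, tetrapyrrole synthesis, shade avoidance, antioxidant enzymes, sugar and starch, plastid-encoded genes, mitochondrion-encoded genes, reference genes and root markers. The lists for photosystem I, electron transport, plastid transcription, photomorphogenesis, circadian clock, rapid stress, salicylate defence, glucosinolate synthesis and guard cells had 1 or 2 members, whose values are given without a set test. The remaining lists had 0 named members (heat shock, jasmonate, carbon starvation, nitrogen assimilation and markers of flower, seed, vasculature and dividing cells). The set test was camera in limma with a preset correlation of 0.01, and p was adjusted over the tested lists within a comparison. Camera with an estimated correlation and fry were run beside it. Where a gene had several probe sets, the brightest was taken.

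The alternatives fixed in advance were quantile normalization, centring each array on the same median, filters at the 30th percentile and the median of signal, a trended robust variance, array weights, a fit to only the groups compared, the replicate number as a block, a 2-fold minimum, and leaving out each array in turn. Further alternatives were chosen after seeing the data. The first was a covariate called here the within-group axis. It is the first principal component of the residuals around the group means, with 28% of the within-group variance, and it was estimated from the same values that it adjusts. The others were the mean 3' to 5' difference of the actin, GAPDH and ubiquitin control probe sets (a measure of RNA integrity), the poly-A spikes, and leaving out both WT 0 min arrays farthest out on the first principal component. These arrays, replicates 1 and 3, are called outlying for that position alone. They scored -53.4 and -54.8 there, and replicate 2 scored -26.3. The same component set WT 0 min (mean -44.8) apart from the other groups (-7.7 to 24.1). Leaving them out brings WT 0 min nearer the other groups by selection, so a lower count without them is no test of outliers. The standard error with a covariate is given as a multiple of that without it, as the median over all 22746 probe sets. This multiple need not hold for the called ones. The tests were checked on simulated data with 200 changed probe sets, known lists and independent noise in each probe set.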

Results

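The expression of 22746 probe sets was compared across 18 arrays of rosette leaves, 3 for each of 6 groups. The groups were WT (Col-0) and the *stn7* knockout, sampled in PSI light (0 min) and 30 min and 60 min after the shift to PSII light. STN7 is a thylakoid kinase that responds to the redox state of plastoquinone, and the labels use the mutant as the control that does not perceive this signal. No group stayed in PSI light for 30 or 60 min, so within a genotype the light shift and the time of harvest are confounded. Changes are log2 fold changes ± the moderated standard error (SE) from limma, with n = 3 arrays per group, and p is adjusted. Genes given as the largest changes between a pair of groups had all 3 arrays of 1 group above all 3 of the other. Within a genotype the comparisons of 30 and 60 min with 0 min share the 0 min arrays, as do both genotype differences in response. Their values are therefore not independent of each other.

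The first principal component held 39.8% of the variance and the second 19.6%. Correlations between arrays of 1 group ran from 0.9896 to 0.9967. Arrays also differed within groups along a common axis, the within-group axis. Its mean score was 32.9 ± 20 (SD, n = 3) in WT at 0 min, -14.8 ± 7 at 30 min and -14.9 ± 4.6 at 60 min. In *stn7* it was -2.9 ± 20.4, -15.4 ± 12.4 and 15.1 ± 15.1. The 3' to 5' difference of the control probe sets was 1.39 ± 0.16 in *stn7* at 60 min and between 1.06 and 1.19 as a mean in the other groups.

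**Figure D1:**
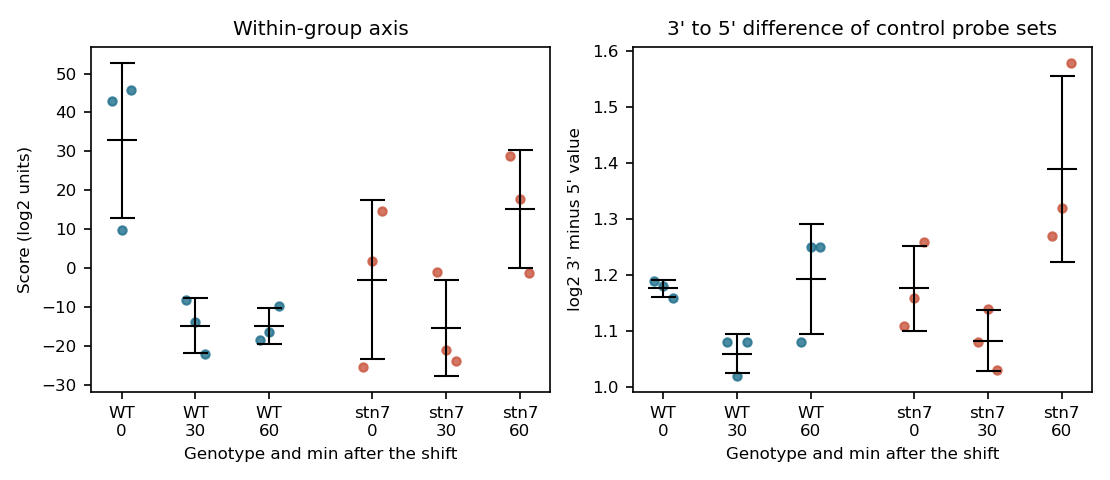
Score on the within-group axis (left, log2 units) and log2 3' minus 5' value of the control probe sets (right) for each array, by genotype and min after the shift, where points are arrays, long lines are means and bars are SD (n = 3). The WT 0 min group has the highest mean axis score, 32.9, and *stn7* at 60 min the highest mean 3' to 5' difference, 1.39.

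The probe set with the largest fall in *stn7* at every time is one for which the annotation used here gives no gene. It was singled out after its values were seen. In WT its log2 value was 8.81 ± 0.1 (SD, n = 3) at 0 min, 8.71 ± 0.18 at 30 min and 8.7 ± 0.31 at 60 min, and in *stn7* it was 4.16 ± 0.17, 4.28 ± 0.11 and 4.18 ± 0.23. Over all times it was lower in *stn7* by 4.53 ± 0.09 on the log2 scale (adjusted p = 1.23e-16), in 9 of 9 arrays. The array medians were 6.1 to 6.31 and the lowest values 2.53 to 2.67, so background can make up part of the *stn7* values and the difference can be larger than given.

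The first question was which transcripts responded in WT within 30 min of the shift. IAA29, an auxin-responsive gene of the Aux/IAA family, fell by 2.5 ± 0.22 on the log2 scale (adjusted p = 4.61e-06). AT5G12050 (-2.61 ± 0.23) and AT5G02580 (-2.58 ± 0.27) fell the most among the named genes, followed by AT4G33666 (-2.14), AT1G49210 (-2.14), AT2G20670 (-2.12), AT3G07350 (-1.84), AT1G23390 (-1.82), AT1G54020 (-1.67) and AT1G49200 (-1.61). The largest rises were those of AT5G16730 (2.59 ± 0.44, adjusted p = 0.000602), AT3G29075 (2.58 ± 0.47) and AT5G66060 (2.54 ± 0.44). AT2G44200, AT1G64330, AT1G74250, AT2G02160, AT2G40650, AT1G47970 and AT4G02720 rose by 2.09 to 2.38. WRKY53, a stress and senescence regulator, rose by 1.06 ± 0.3, and UGT74B1, a glucosyltransferase of glucosinolate synthesis, by 1.23 ± 0.24.

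Of the 16 mitochondrion-encoded genes, 7 fell in WT at 30 min and 1 rose (10 and 1 when adjusted over the list alone). Cytochrome oxidase gene cox2 changed by -1.17 ± 0.18 and nad6 of complex I by -1.03 ± 0.16, while ccb382 rose by 0.55 ± 0.16. The list mean was -0.4 (camera adjusted p = 0.00319; adjusted p = 0.488 with an estimated correlation). In tetrapyrrole synthesis, the route to chlorophyll, CHLM fell (-0.39 ± 0.11) and GSA1 rose (0.74 ± 0.14). The Calvin-Benson enzyme gene SBPASE rose by 0.58 ± 0.14 and PWD, of starch breakdown, by 0.4 ± 0.13. Among the 69 plastid-encoded genes psbK (1.18), psbI (1.14) and rps19 (0.86) rose and psbA (-0.55) and psbH (-0.51) fell. The reference gene UBC21 fell as well (-0.5 ± 0.11).

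In all, 6267 probe sets changed in WT at 30 min, 3184 higher and 3083 lower. With each array centred on its median, which moved this comparison by 0.1, the split was 2427 higher and 4644 lower. With the within-group axis as a covariate 85 passed, and without both outlying WT 0 min arrays 250. With the axis 9 of the 10 named falls passed (not AT1G54020), and 0 of the 10 named rises, whose changes went from between 2.09 and 2.59 to between 0.02 and 0.68. The SE of these rises went from between 0.41 and 0.53 to between 0.24 and 0.44. That of IAA29, a named fall, grew from 0.22 to 0.33. Without WT 0 min replicate 1 the count was 3997. AT1G54020 was not called without that array (adjusted p = 0.0531) or without WT 30 min replicate 3 (adjusted p = 0.0508).

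By 60 min in WT the shade avoidance list, genes that rise in light with little red relative to far red, had fallen. IAA29 changed by -4.48 ± 0.22 from 0 min (adjusted p = 1.2e-09) to a log2 value of 5.12 ± 0.19, under the array medians, where background can make the fall look smaller. HAT2, an HD-Zip regulator, changed by -1.47 ± 0.11 and YUC2, of auxin synthesis, by -0.34 ± 0.12. All 3 measured members fell, also when adjusted over the list alone. The mean was -2.096, or -2.217 relative to the median shift of 0.12 (camera adjusted p = 0.00132; adjusted p = 0.025 with an estimated correlation). AT5G12050 (-3.49 ± 0.23), AT5G02580 (-3.44 ± 0.27) and AT3G62950 of the glutaredoxin family (-2.54 ± 0.15) fell strongly too. They were followed by AT1G49210 (-2.44), SIS (-2.35), AT5G02540 (-2.24), AT2G20670 (-2.23), AT5G03230 (-2.21) and AT3G15450 (-2.09).

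CML38, which encodes a calmodulin-like calcium sensor, rose 13.14-fold (3.72 ± 0.64, adjusted p = 0.000274). AT1G72900 (2.68 ± 0.25) and AT1G72920 (2.4 ± 0.43), which encode TIR-domain proteins, rose, as did AT1G74450 (2.56) and AT3G01830 (2.39). The other named rises were AT3G29075 (3.16), AT5G16730 (2.73), AT1G64330 (2.71), AT5G66060 (2.61) and AT2G44200 (2.51). ZAT10, a zinc finger regulator of the rapid stress list, rose by 1.63 ± 0.4, WRKY53 by 1.44 ± 0.3, UGT74B1 by 1.73 ± 0.24 and HYH, the bZIP homologue of HY5, by 0.83 ± 0.22. GSA1 (0.67 ± 0.14) and PWD (0.39 ± 0.13) rose and CHLM (-0.45 ± 0.11) and the photosystem II gene PSB27 (-0.31 ± 0.1) fell. The reference genes UBC21 (-0.51) and SAND (-0.35) fell.

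Of 69 plastid-encoded genes 13 rose in WT at 60 min and 0 fell (11 and 0 when adjusted over the list alone), led by rpl14 (1.4 ± 0.34), rpl16 (1.3 ± 0.33), psbC (1.14 ± 0.27) and psaB (1.05 ± 0.24). The plastid mean was 0.299, or 0.178 relative to the median shift (camera adjusted p = 0.00916; adjusted p = 0.761 with an estimated correlation). Without WT 0 min replicate 2 it was 0.453, without replicate 3 it was 0.105 (adjusted p = 0.639), without WT 60 min replicate 3 it was 0.193 (adjusted p = 0.234), and with the axis as a covariate it was -0.134 (adjusted p = 0.367). Of 16 mitochondrion-encoded genes 9 fell and 0 rose (9 and 1 when adjusted over the list alone), among them cox2 (-1.01 ± 0.18) and nad1 (-1 ± 0.19). Their mean was -0.387, or -0.508 relative to the median shift (camera adjusted p = 0.00916; adjusted p = 0.644 with an estimated correlation).

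**Figure D2:**
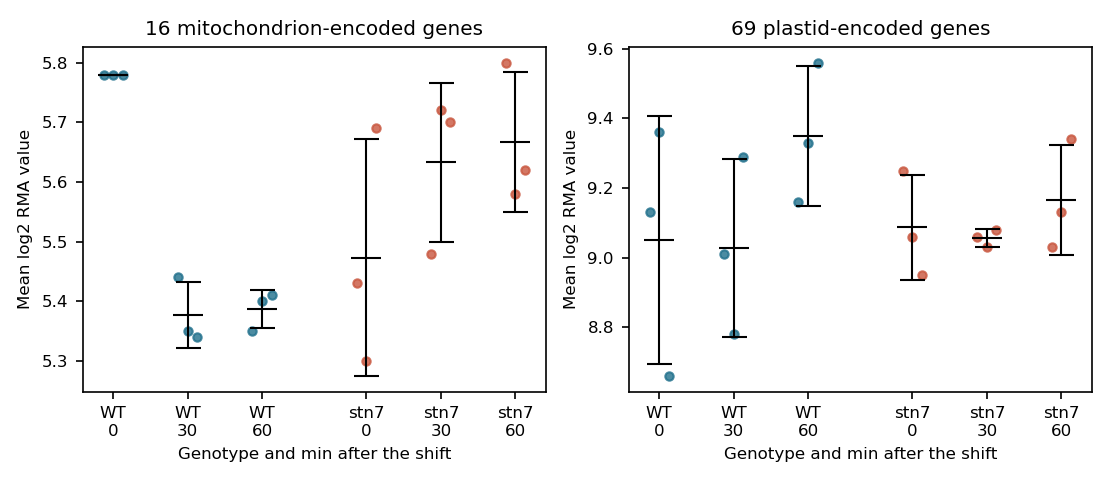
Mean log2 RMA value of 16 mitochondrion-encoded genes (left) and 69 plastid-encoded genes (right) for each array, by genotype and min after the shift; points are arrays, long lines are means and bars are SD (n = 3). The WT 0 min arrays all sit at 5.78 for the mitochondrial list, and every WT array at 30 or 60 min lies between 5.34 and 5.44.

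At 60 min 7439 probe sets differed from 0 min in WT, 3688 higher and 3751 lower, or 2874 higher and 6287 lower after median centring. With the axis as a covariate the median size of the called changes went from 0.58 to 0.32. Over all probe sets, called or not, the SE grew 1.49 times at the median. The count with the axis was 1272, with all 10 named falls and 6 of the 10 named rises past the threshold (not AT5G16730, AT1G64330, AT5G66060 and AT2G44200). Without both outlying WT 0 min arrays it was 1937.

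Between 30 and 60 min in WT the shade avoidance genes IAA29 (-1.99 ± 0.22) and HAT2 (-1.29 ± 0.11) fell (2 of 3 members, also when adjusted over the list alone). The list mean was -1.133 (camera adjusted p = 9.18e-07; adjusted p = 0.00224 with an estimated correlation). AT5G62280 (-1.46 ± 0.13), SIS (-1.35), AT5G02540 (-1.31), AKINBETA1, a subunit of the energy-sensing kinase SnRK1 (-1.08), AT3G62950 (-1.08), AT5G02550 (-1.01), WES1, which conjugates auxin (-0.98), and AT4G16000 (-0.95) fell. AT1G72920 (2.27 ± 0.43), AT1G72900 (1.78 ± 0.25) and AT1G72940 (1.55 ± 0.29) of the TIR-domain family rose. So did AT3G01830 (1.96), AT4G10270 (1.83 ± 0.19), AT1G14200 (1.47), AT3G14200 (1.31), AT3G05320 (1.3), AT4G24380 (1.3) and AT1G66080 (1.27). Of 69 plastid-encoded genes 1, psbC, was past the threshold (1 when adjusted over the list alone). The list mean was 0.324 (95% interval -0.06 to 0.71; camera adjusted p = 2.44e-10; adjusted p = 0.596 with an estimated correlation). It was 0.201 without WT 30 min replicate 2 and 0.204 with the 3' to 5' covariate.

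This comparison held 258 changed probe sets, 123 higher and 135 lower, with 583 under the axis covariate, 680 with array weights and 46 with the 3' to 5' covariate. The mean axis scores at 30 and 60 min were -14.8 and -14.9, so the axis covariate could hardly remove calls. With the 3' to 5' covariate the median size of the called changes went only from 0.66 to 0.64, and the SE was 1.16 times as large. The count was 55 without WT 30 min replicate 1, 109 without replicate 3, and 150, 94 and 93 without WT 60 min replicates 1, 2 and 3. Among the named genes AKINBETA1, AT1G72920, AT1G72940, AT3G01830, AT4G16000, AT4G24380 and WES1 were not called without WT 30 min replicate 1 (adjusted p 0.0512, 0.0713, 0.077, 0.148, 0.0558, 0.0698 and 0.2). Without other arrays of these groups AT3G01830 reached 0.224 (WT 60 min replicate 3) and also missed the threshold without WT 30 min replicates 2 and 3 (0.0878 and 0.11) and WT 60 min replicate 2 (0.0828). WES1 missed it without WT 30 min replicate 3 (0.164) and WT 60 min replicates 1 to 3 (0.088, 0.165 and 0.121). AT1G72920 missed it without WT 30 min replicate 3 (0.0624) and WT 60 min replicate 3 (0.0826), as did AT1G72940 without the latter (0.0759) and AT4G24380 without the former (0.0585).

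**Figure D3:**
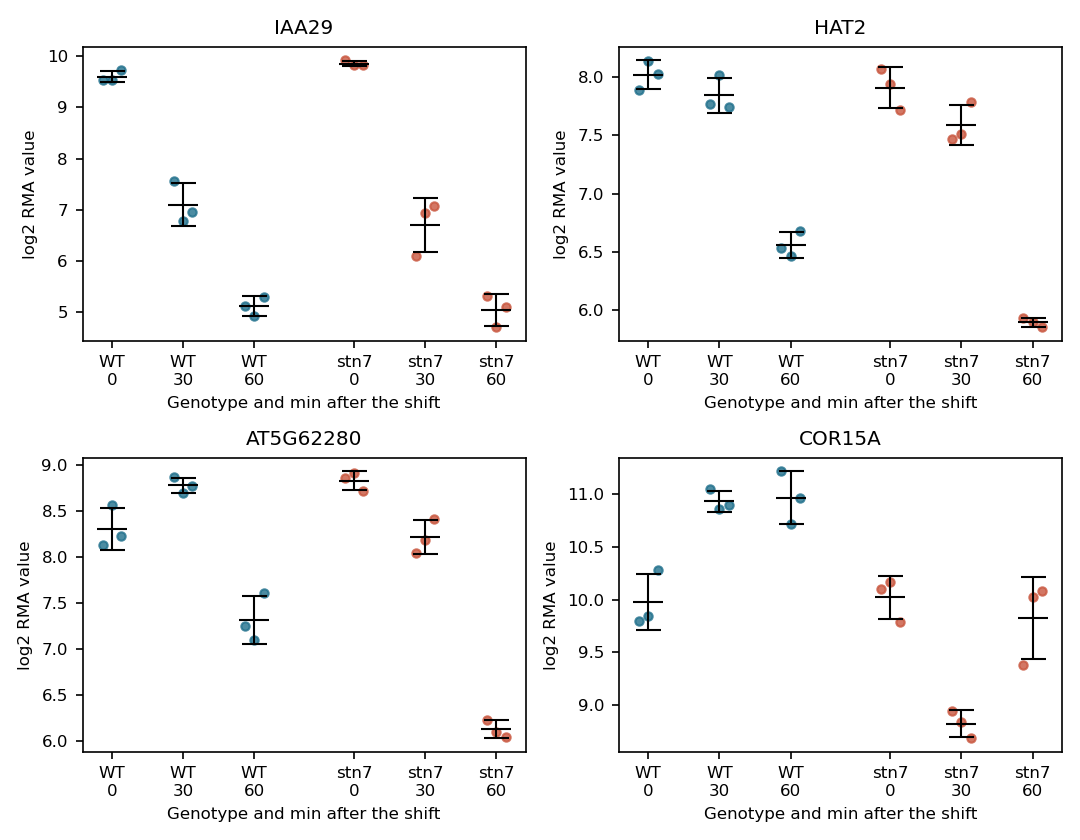
Log2 RMA value of IAA29, HAT2, AT5G62280 and COR15A in each array, by genotype and min after the shift; points are arrays, long lines are means and bars are SD (n = 3). IAA29 lies between 9.53 and 9.92 in every 0 min array and between 4.7 and 5.31 in every 60 min array, in both genotypes.

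In *stn7*, the comparison of 30 min with 0 min asked what responds to the light without the kinase. IAA29 changed by -3.15 ± 0.22 (adjusted p = 1.3e-07). AT3G05730 (-2.88 ± 0.29), AT3G62950 (-2.46 ± 0.15), AT3G07350 (-2.33), AT1G23390 (-2.31), AT2G20670 (-2.26), AT4G33666 (-2.1), AT5G60680 (-1.97), AT2G28400 (-1.93) and AT5G01870 (-1.93) fell. CHI, here the chitinase gene AT2G43570, rose by 2.07 ± 0.23 (adjusted p = 3.93e-05) and the ubiquitin ligase gene RING1 by 1.62 ± 0.29. AT3G19680 (1.42), AT5G52750 (1.32), AT1G20823 (1.29), AT5G17760 (1.23), AT1G30250 (1.19), AT5G35735 (1.15), AT4G27280 (1.15) and AT3G15310 (1.15) rose. GI, a clock gene, rose by 0.66 ± 0.1. PORB (-0.4 ± 0.11) and CHLM (-0.46 ± 0.11) of chlorophyll synthesis, BCAT4 of glucosinolate synthesis (-0.85 ± 0.2) and the guard cell marker GC1 (-0.73 ± 0.17) fell. The mitochondrial genes nad5 (0.71) and nad9 (0.6) rose.

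The shade avoidance mean was -1.192 in *stn7* at 30 min, with 1 of 3 members past the threshold and 2 when adjusted over the list alone (camera adjusted p = 0.00302; adjusted p = 0.0366 with an estimated correlation). In WT at 30 min it was -0.963 (camera adjusted p = 0.0816). In all, 1649 probe sets changed in *stn7* at 30 min, 789 higher and 860 lower, or 500 higher and 1140 lower after median centring. Array weights gave 2597. The count was 1011 without *stn7* 0 min replicate 2, 840 without replicate 3, 909 without *stn7* 30 min replicate 2 and 684 without replicate 3. AT4G27280 and AT5G52750 were not called without *stn7* 0 min replicate 3 (adjusted p 0.229 and 0.08) or *stn7* 30 min replicate 2 (0.0666 and 0.0535). AT4G27280 was also not called without *stn7* 0 min replicate 1 (0.0799) or *stn7* 30 min replicates 1 and 3 (0.155 and 0.0839).

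At 60 min in *stn7* the largest falls were those of IAA29 (-4.82 ± 0.22, adjusted p = 3.45e-10, to 5.03 ± 0.3, again under the array medians), AT3G62950 (-3.16 ± 0.15), AT5G12050 (-2.72), AT5G02580 (-2.72) and AT5G62280 (-2.7 ± 0.13). AT3G05730 (-2.36), AT5G03230 (-2.12), HAT2 (-2.02 ± 0.11), AT3G15450 (-2.02) and AT3G07350 (-1.99) fell as well. The shade avoidance mean was -2.328, with 2 of 3 members past the threshold (2 when adjusted over the list alone; camera adjusted p = 1.42e-05; adjusted p = 0.00432 with an estimated correlation). AT3G14200 (2.13 ± 0.19), AT1G72920 (2.13 ± 0.43), AT4G21870 (2.05) and EXO, a brassinosteroid-responsive gene (1.94 ± 0.31), rose the most. AT3G28270 (1.78), AT3G15310 (1.78), AT1G61890 (1.78), AT4G10270 (1.76), AT4G16563 (1.75) and AT3G04210 (1.64) followed. HYH (0.82 ± 0.22) and GI (0.61 ± 0.1) rose.

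In *stn7* at 60 min, where the 3' to 5' difference was 1.39 ± 0.16 against 1.18 ± 0.07 at 0 min, all 3 measured photosystem II subunits fell relative to 0 min. They were PSB27 (-0.54 ± 0.1), PSBY (-0.5 ± 0.09) and PSBW (-0.3 ± 0.09), 3 also when adjusted over the list alone (mean -0.446, camera adjusted p = 0.00358; adjusted p = 0.117 with an estimated correlation). Of the light-harvesting antenna genes LHCB4.1, LHCB4.2 and LHCB4.3, 1 fell, LHCB4.2 (-0.61 ± 0.1), and 2 when adjusted over the list alone (mean -0.346, camera adjusted p = 0.0254; adjusted p = 0.241 with an estimated correlation). That list was not called without *stn7* 0 min replicate 1 (-0.288, adjusted p = 0.0552) or *stn7* 60 min replicate 1 (-0.275, adjusted p = 0.0749). In tetrapyrrole synthesis PORB (-0.6 ± 0.11) and CHLM (-0.63 ± 0.11) fell, 2 of 3 also over the list alone (mean -0.469, camera adjusted p = 0.013; adjusted p = 0.128 with an estimated correlation). PSAN of photosystem I (-0.35 ± 0.11), PRK of the Calvin-Benson cycle (-0.39 ± 0.12), TSP9, a thylakoid phosphoprotein (-0.39 ± 0.12), and the ascorbate peroxidase TAPX (-0.5 ± 0.11) fell, and SAPX rose (0.38 ± 0.1).

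Among mitochondrial genes cox2 (0.83 ± 0.18), nad5 (0.55), ccb452 (0.54) and nad9 (0.41) rose in *stn7* at 60 min. Among plastid genes petB rose (0.4) and atpA fell (-1.56 ± 0.52). In all, 3769 probe sets changed, 2013 higher and 1756 lower, with 3558 under the axis covariate and 1805 with the 3' to 5' covariate. With the latter the median size of the called changes was 0.58 against 0.56, and the SE was 1.35 times as large, so the lost calls do not speak for RNA integrity as a cause. Of the 20 named genes 20 passed with the axis and 19 with the 3' to 5' covariate.

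From 30 to 60 min in *stn7*, AT1G14200 (2.6 ± 0.21, adjusted p = 3.73e-06) and AT3G14200 (2.17 ± 0.19) rose the most. AT5G64850 (1.67), AT1G54050 (1.67), AT4G21870 (1.64), AT4G10270 (1.59), AT1G66080 (1.57), AT1G72920 (1.5), AT4G16563 (1.44) and AT2G31730 (1.44) rose. AT5G62280 (-2.09 ± 0.13, adjusted p = 2.03e-07) and TGH, of RNA processing (-1.85 ± 0.19), fell, as did AT2G02160 (-2.5 ± 0.47), AT2G01100 (-2.17), NET4B, an actin-binding protein gene (-2.05), AT1G15940 (-2.04), AT5G66060 (-1.98), AT1G15200 (-1.97), AT1G22930 (-1.89) and AT4G08310 (-1.83). HAT2 (-1.7 ± 0.11) and IAA29 (-1.67 ± 0.22) fell, 2 of 3 shade avoidance members, also over the list alone (mean -1.136, camera adjusted p = 0.00179; adjusted p = 0.0287 with an estimated correlation). LHCB4.2 (-0.48), PSBY (-0.43), PSB27 (-0.4), GSA1 (-0.46) and UGT74B1 (-0.85) fell. GC1 (1.23 ± 0.17), HYH (0.84), petA (0.7) and ccsA (0.56) rose.

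The later interval in *stn7* held 3702 changed probe sets, 1675 higher and 2027 lower, or 2263 higher and 1623 lower after median centring. With the 3' to 5' covariate the count was 66, and of the 20 named genes AT1G14200, AT3G14200, AT5G62280 and TGH passed. The median size of the called changes went only from 0.55 to 0.54, and the SE was 1.61 times as large, so the lost calls do not show that RNA integrity made the changes. The axis covariate gave a count of 1110, and 9 of the 10 rises and 6 of the 10 falls passed. The count was 2302 without *stn7* 30 min replicate 2, 1551 without replicate 3, 2279 without *stn7* 60 min replicate 1 and 2295 without replicate 2. AT1G72920 and AT1G15200 were not called without *stn7* 30 min replicates 2 and 3 (adjusted p 0.0839 and 0.12, and 0.0636 and 0.0789) or *stn7* 60 min replicate 2 (0.0884 and 0.0516). AT1G72920 was also not called without *stn7* 60 min replicate 3 (0.0875) and AT1G15200 without replicate 1 (0.0573).

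The responses of the genotypes overlapped. At 30 min 313 probe sets rose in both and 531 fell in both, where independent lists of these sizes would share 110.4 and 116.6, and 26 went opposite ways. At 60 min 679 rose in both and 803 fell in both (326.4 and 289.6 for independent lists), and 474 went opposite ways (616.7). From 30 to 60 min 80 rose and 96 fell in both (9.1 and 12), and 0 went opposite ways (20.9). Spearman correlations of the fold changes across probe sets, which are not independent replicates, were 0.46, 0.09 and 0.34.

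**Figure D4:**
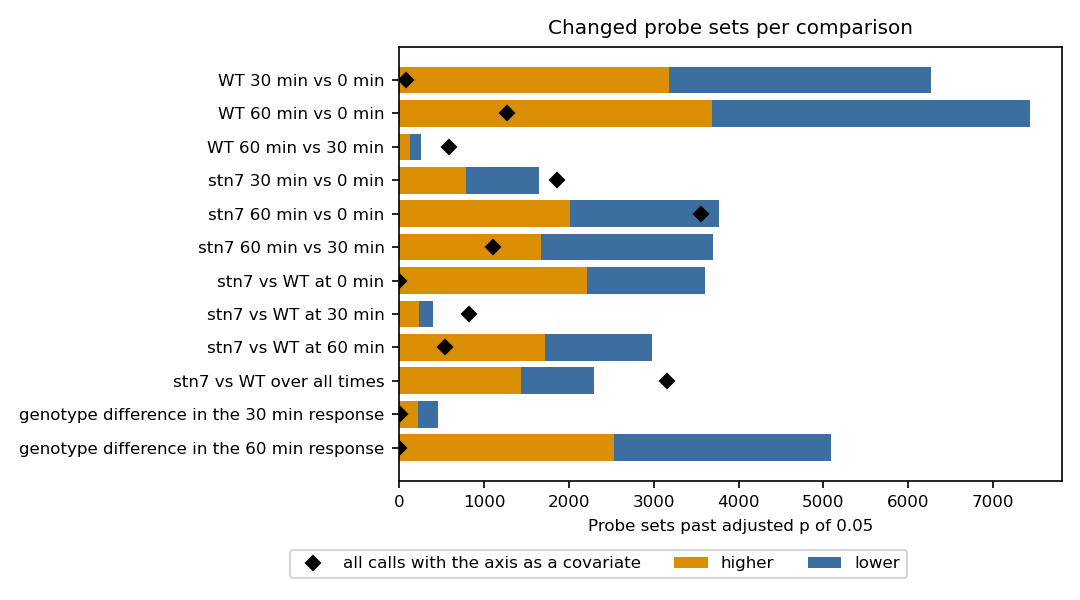
Number of probe sets higher and lower at an adjusted p under 0.05 in each of the 12 comparisons, where black diamonds are all calls with the within-group axis as a covariate (n = 3 arrays per group). The 60 min response of WT has 7439 calls and 1272 with the covariate, and *stn7* against WT over all times has 2292 and 3153.

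In PSI light, before the shift, *stn7* was compared with WT for effects of the mutation alone. QQS, an orphan gene linked to starch content, was lower in *stn7* (-1.77 ± 0.23, adjusted p = 0.00112), as were CHI (-1.27 ± 0.23), AT1G76960 (-1.2), AT5G39670 (-1.07), AT1G01640 (-1.03), AT1G21520 (-1.02), AT3G48020 (-1), AT4G19430 (-0.99), AT5G02580 (-0.93) and AT2G18010 (-0.93). AT3G13190 (1.54 ± 0.3, adjusted p = 0.00554), AT5G50740 (1.54), AT4G22000 (1.52), AT2G01100 (1.5), AT5G10290 (1.47), AT3G19650 (1.39), AT4G00270 (1.37), VPS24.1, of membrane sorting (1.37), AT1G02330 (1.37) and AT3G52220 (1.36) were higher. APL4, of starch synthesis (0.54 ± 0.14), and UGT74B1 (0.81 ± 0.24) were higher, and BCAT4 (-0.81 ± 0.2), GI (-0.33 ± 0.1), rps18 (-0.56) and UBC21 (-0.34) lower. Of 16 mitochondrion-encoded genes 8 were lower, led by cox2 (-0.93 ± 0.18), and nad2 was higher (0.78 ± 0.26), with 10 lower and 1 higher when adjusted over the list alone. Their mean was -0.301, or -0.41 relative to the median shift of 0.11 (camera adjusted p = 0.00612; adjusted p = 0.8 with an estimated correlation; without *stn7* 0 min replicate 2 -0.216, adjusted p = 0.137).

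At 0 min 3609 probe sets differed, 2211 higher and 1398 lower in *stn7*, and after median centring 1650 higher and 4079 lower. At a 2-fold minimum 275 were higher and 13 lower. With the axis as a covariate 3 passed, the probe set with the largest fall in *stn7*, AT4G18260 (0.93 ± 0.15) and AT2G19970 (1.21 ± 0.17), against 2355 at an unadjusted p under 0.05. These 3 were singled out after their values were seen, and none of the 20 named genes passed with that covariate in limma. The 10 named as higher went from between 1.36 and 1.54 to between 0.37 and 0.7. The changes of CHI (-1.27 ± 0.23 to -1.22 ± 0.3), AT4G19430 (-0.99 ± 0.19 to -0.82 ± 0.24) and AT2G18010 (-0.93 ± 0.14 to -0.82 ± 0.18) stayed nearer their size, with a larger SE. QQS went from -1.77 ± 0.23 to -1.26 ± 0.24, and the other 6 named as lower to between -0.61 and -0.43. In a fit to these 6 arrays 1 passed, the same probe set with the largest fall, against 5939 at an unadjusted p under 0.05. The count was 1325 without WT 0 min replicate 1, 664 without WT 0 min replicate 3, 877 without *stn7* 0 min replicate 1 and 1991 without *stn7* 0 min replicate 2. Without WT 0 min replicate 3 the named genes AT1G02330, AT1G76960, AT2G01100, AT3G48020, AT3G52220, AT4G00270, AT5G02580, AT5G10290 and AT5G39670 were not called (adjusted p 0.064, 0.118, 0.0609, 0.136, 0.0571, 0.0701, 0.143, 0.0688 and 0.104). Without *stn7* 0 min replicate 1 the same 9 were not called (0.0572, 0.116, 0.068, 0.0715, 0.0502, 0.0699, 0.138, 0.0544 and 0.109). Without WT 0 min replicate 1 AT1G76960, AT2G01100, AT3G48020, AT4G00270, AT5G02580 and AT5G39670 were not called (0.0586, 0.0561, 0.0888, 0.0607, 0.102 and 0.0591), and without *stn7* 0 min replicate 2 AT3G48020 was not (0.0728).

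At 30 min after the shift COR15A and COR15B, which encode cold-regulated proteins of the chloroplast stroma, were lower in *stn7* than in WT (-2.12 ± 0.18, adjusted p = 5.73e-06, and -1.23 ± 0.18). AT3G05730 (-2.17 ± 0.29), AT5G01870 (-1.79), AT1G14200 (-1.47), AT5G33370 (-1.43), AT2G33850 (-1.42), AT3G62950 (-1.21), BCAT4 (-1.19 ± 0.2) and AT1G26800 (-1.17) were also lower. AT3G28270 (1.14 ± 0.14, adjusted p = 0.000912), AT1G52000 (1.09), AT3G19680 (1.06), CHI (1.02 ± 0.23), AT2G19970 (0.98), OCT4, a cation transporter gene (0.97), AT1G07050 (0.92), AT3G50650 (0.91), AT4G30990 (0.88) and AT5G39940 (0.88) were higher. FAMA, a guard cell regulator, was higher by 0.59 ± 0.12. Of 16 mitochondrion-encoded genes 6 were higher and 0 lower (6 and 1 when adjusted over the list alone), including cox2 (0.8 ± 0.18), nad9 (0.78 ± 0.11) and nad5 (0.75 ± 0.17). Their mean was 0.256 (camera adjusted p = 0.00286; adjusted p = 0.317 with an estimated correlation).

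In all, 404 probe sets differed at 30 min, 238 higher and 166 lower in *stn7*. Median centring gave 107 higher and 259 lower, and quantile normalization 168 and 200. The axis covariate gave 828 and array weights 772, and all 404 passed with the axis. The mean axis scores of WT and *stn7* at 30 min were -14.8 and -15.4, so this covariate could hardly remove calls here. A fit to these 6 arrays gave 194. The count was 165 without WT 30 min replicate 1, 150 without WT 30 min replicate 2, 152 without *stn7* 30 min replicate 2 and 92 without *stn7* 30 min replicate 3. Of the named genes CHI, AT3G19680, AT1G07050 and AT1G26800 were not called without WT 30 min replicate 1 (adjusted p 0.0963, 0.0988, 0.0798 and 0.0532). Without *stn7* 30 min replicate 3 the first 3 of these were not called (0.143, 0.104 and 0.117). CHI also missed the threshold without WT 30 min replicate 2 (0.116) and *stn7* 30 min replicates 1 and 2 (0.0662 and 0.091), AT3G19680 without WT 30 min replicate 2 (0.0733) and *stn7* 30 min replicate 1 (0.0701), and AT1G07050 without WT 30 min replicate 3 (0.0911) and *stn7* 30 min replicate 2 (0.0886).

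At 60 min THI2.1, which encodes an antimicrobial thionin, was higher in *stn7* (1.98 ± 0.47, adjusted p = 0.0106), as were SPT, a bHLH regulator of growth (1.17 ± 0.19), THE1, a receptor kinase that senses cell walls (1.07 ± 0.15), and XTH16, a cell wall enzyme gene (1.05 ± 0.22). AT3G28270 (1.42 ± 0.14, adjusted p = 4.61e-05), AT3G28220 (1.39), AT4G21870 (1.32), AT5G65380 (1.21), AT4G33420 (1.2) and AT4G26790 (1.09) were higher too. AT3G29075 (-2.45 ± 0.47, adjusted p = 0.00342), NET4B (-2.45), AT4G08310 (-2.3), AT5G66060 (-2.3), AT2G02160 (-2.3), AT1G15200 (-2.14), AT1G64330 (-2.1), AT2G40650 (-2), AT5G16730 (-1.98) and AT5G52280 (-1.92) were lower. Of the fixed lists HAT2 (-0.66 ± 0.11), BCAT4 (-1.1 ± 0.2), UGT74B1 (-1.15 ± 0.24), LHCB4.2 (-0.33), PSBY (-0.29), SBPASE (-0.47), GSA1 (-0.45), rpl14 (-1.11), rpl16 (-1.02) and ccb382 (-0.64) were lower. The mitochondrial genes cox2 (0.91), ccb452 (0.67), nad1 (0.63), nad5 (0.63) and nad9 (0.58) and the root marker PYK10 (0.52) were higher.

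At 60 min 2974 probe sets differed, 1714 higher and 1260 lower in *stn7*, and at a 2-fold minimum 26 higher and 352 lower. The count was 546 under the axis covariate, 1151 with the 3' to 5' covariate and 4549 with array weights. Of the 10 named rises and 10 named falls, 7 and 5 passed with the axis and 8 and 4 with the 3' to 5' covariate. The median size of all called changes was 0.54 as reported, 0.39 with the axis and 0.58 with the 3' to 5' covariate. The SE was 1.2 and 1.3 times as large with these covariates. The count was 1884, 1644 and 1732 without WT 60 min replicates 1, 2 and 3, and 1265 and 1538 without *stn7* 60 min replicates 1 and 2. Without *stn7* 60 min replicate 1 AT1G15200, AT1G64330, AT2G40650 and THI2.1 were not called (adjusted p 0.0541, 0.0541, 0.0524 and 0.0515).

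Averaged over the 3 times, AT3G05730 (-1.26 ± 0.16), QQS (-1.14 ± 0.13), COR15A (-1.07 ± 0.1, adjusted p = 1.54e-05) and BCAT4 (-1.03 ± 0.12), which encodes an aminotransferase of methionine-derived glucosinolates, were lower in *stn7*. AT5G01870 (-1.02), AT2G37130 (-1.01), LTI30, a dehydrin gene (-0.96), AT2G33850 (-0.93), AT5G33370 (-0.9) and AT2G25625 (-0.8) were lower too. THI2.1 (1.13 ± 0.27), AT3G28270 (1.03 ± 0.08, adjusted p = 4.45e-06), AT4G16563 (0.97), AT2G19970 (0.86), AT3G28220 (0.85), THE1 (0.83 ± 0.09), AT1G52000 (0.76), EXO (0.71 ± 0.18), AT5G65380 (0.69) and AT1G07050 (0.63) were higher. Of the list members FAMA (0.38), PYK10 (0.32) and APL4 (0.28) were higher, and HAT2 (-0.34), LHCB4.3 (-0.21), psaJ (-0.77), rpl33 (-0.56) and rps18 (-0.4) lower. The mitochondrial genes nad2 (0.56), nad9 (0.37), nad4L (0.32) and ccb452 (0.27) were higher and ccb382 (-0.4) lower. In all, 2292 probe sets differed, 1437 higher and 855 lower, or 795 and 1744 after median centring. All 2292 passed with the axis as a covariate, where the count was 3153. Across probe sets the loading on the axis hardly correlated with this difference (-0.09), and the SE was 0.97 times as large. The covariate could hardly remove calls here, so that all passed says little about their stability. Array weights gave 3558, the 3' to 5' covariate 1353 and the fit without both outlying WT 0 min arrays 1172. Of the 20 named genes THI2.1 (1.06 ± 0.31, adjusted p = 0.0539), EXO (0.67 ± 0.21, adjusted p = 0.0677) and LTI30 (-0.88 ± 0.27, adjusted p = 0.0698) did not pass with the 3' to 5' covariate.

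The genotype difference in response asks which changes after the shift differ without STN7. In the 30 min response COR15A differed by -2.17 ± 0.25 (adjusted p = 0.000822), with a rise of 0.96 in WT and a fall of -1.21 in *stn7*, and CHI by 2.28 ± 0.33. The mitochondrial genes cox2 (1.73 ± 0.26), nad5 (1.37 ± 0.24) and nad1 (1.28) were among the 10 largest differences upward. This nad1 value is from a probe set other than the one counted for the list, which gave 0.73 (adjusted p = 0.145). The mitochondrial list, 6 of 16 higher and 0 lower (9 and 0 when adjusted over the list alone), had a mean of 0.557 (camera adjusted p = 2.83e-06; adjusted p = 0.233 with an estimated correlation). In all, 463 probe sets differed, 217 upward and 246 downward, with 11 under the axis covariate, 1500 with array weights, 304 with the 3' to 5' covariate and 910 with the poly-A spikes as a covariate. Without both outlying WT 0 min arrays 3 passed, against 1721 at an unadjusted p under 0.05: COR15A and 2 probe sets without 1 gene of their own, singled out after their values were seen. The count was 18, 2216 and 23 without WT 0 min replicates 1, 2 and 3, and 25 and 114 without WT 30 min replicates 2 and 3. It was 26, 84 and 1179 without *stn7* 0 min replicates 1, 2 and 3, and 120, 83 and 32 without *stn7* 30 min replicates 1, 2 and 3. The genes nad5 and nad1 were not called without WT 0 min replicate 1 (adjusted p 0.0664 for both), WT 0 min replicate 3 (0.0597 and 0.0607) or *stn7* 30 min replicate 3 (0.0532 and 0.0552), nor nad1 without *stn7* 0 min replicate 1 (0.0579).

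In the 60 min response AT3G29075 (-4.1 ± 0.66, adjusted p = 0.000724) and NET4B (-3.82 ± 0.67) differed most downward, and THI2.1 (2.16 ± 0.66), SPT (1.87 ± 0.27) and cox2 (1.84 ± 0.26) were among the largest upward. Of the mitochondrial genes 7 of 16 were higher and 0 lower (9 and 1 when adjusted over the list alone), with a mean of 0.577, or 0.703 relative to the median shift of -0.13 (camera adjusted p = 0.00293; adjusted p = 0.457 with an estimated correlation). In all, 5091 probe sets differed, 2528 upward and 2563 downward, or 4341 and 2106 after median centring, and at a 2-fold minimum 190 upward and 1226 downward. With the axis as a covariate limma called 0, against 1948 at an unadjusted p under 0.05, and without both outlying WT 0 min arrays 742. THI2.1 was not called without WT 0 min replicate 1 (adjusted p = 0.0688), WT 60 min replicate 3 (0.0524), *stn7* 0 min replicates 1 and 2 (0.0768 and 0.0673) or *stn7* 60 min replicates 1 and 2 (0.0617 and 0.0538). The other named genes of both responses are given among the results for a closer look.

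Some lists did not pass with camera in any of the 12 comparisons, at the preset or the estimated correlation. Their lowest camera adjusted p was 0.164 for thylakoid kinases and phosphatases (*stn7* at 60 min against 0 min), 0.0826 for the Calvin-Benson cycle and 0.312 for reference genes (both *stn7* against WT at 60 min), 0.223 for antioxidant enzymes (*stn7* against WT at 30 min), and 0.351 for both sugar and starch and root markers (genotype difference in the 60 min response). By fry, which tests whether the genes of a list move 1 way and not whether they differ from other genes, the lowest adjusted p of these lists was 0.00852, 0.0216, 0.00172, 0.0412, 0.0914 and 0.015, with sugar and starch the fifth and root markers the sixth. ATPC1 of electron transport, RPOTMP of plastid transcription, DFR of the photomorphogenesis list and AAA-ATPASE of the rapid stress list passed in 0 of the 12 comparisons in limma.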

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

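Apart from the fall of the shade avoidance list, a large change within WT, the results here stand out because the response to the light shift differed between *stn7* and WT in a test of the difference itself. The explanations weighed below were tested only after the results were seen, while the regroupings of the arrays were planned. Other groupings of the same arrays were counted for every comparison. For the pairs of groups, 3 arrays against 3 allow only 10 splits, so that no share under 0.1 can arise. The real counts were 6267, 7439, 258, 1649, 3769, 3702, 3609, 404 and 2974 for the 6 time comparisons (WT, then *stn7*) and the genotypes at 0, 30 and 60 min, and in each 1 of the 10 splits, the real one, gave as many. The highest of the other splits gave 0, 0, 0, 191, 1, 0, 415, 0 and 2. For the mean over all times and both responses, 100 relabellings of genotype within each time were drawn, and for each a share under 0.05 gave as many calls. Such a relabelling removes any genotype difference, also one present at every time. It therefore cannot test by itself whether the difference in response arose by chance. For *stn7* against WT over all times, 2292 probe sets stood against 1502 as the highest other, and 1 of the 100, the real one, gave as many. For the 30 min response 463 stood against 2848, and 2 of the 100 gave as many. For the 60 min response 5091 stood against 4087, and 1 of the 100 gave as many. The labelling with 4087 kept 3 of 3 *stn7* arrays at 60 min and 2 of 3 at 0 min, so it lies close to the real one. That with 1502 kept 0, 1 and 3 of the *stn7* arrays at 0, 30 and 60 min. The labelling with 2848 exchanged all arrays of the genotypes at 30 min and none at 0 min, so it sums the genotype differences of the 2 times. So high a count may therefore come from a genotype difference at 1 of these times or from one shared by both. At 0 min 3609 probe sets differed between the genotypes and at 30 min 404.

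The first pattern weighed is the 5091 probe sets whose 60 min response differed between genotypes. RNA integrity is argued against as the whole cause, since 3698 of the calls stayed with the 3' to 5' covariate. With the poly-A spikes 4959 stayed. The mean spike values at 0 and 60 min were 7.24 and 7.19 in WT and 7.18 and 7.23 in *stn7*. This covariate could therefore hardly remove calls, and the 4959 say little about the amount of sample RNA. An array difference that also runs between replicates may account for them, because across probe sets the loading on the within-group axis correlated with the fold change at 0.79. With the axis as a covariate the median size of the called changes went from 0.75 to 0.35. Limma then called 0, against 1948 at an unadjusted p under 0.05. Over all probe sets, called or not, the SE grew 1.47 times at the median, which need not hold for the calls. The genotype difference in the 60 min change of the axis score was 65.8 (permutation p = 0.01, 400 arrangements of genotype within 0 min and within 60 min). Such arrangements also remove a genotype difference present at both times, and the axis was not estimated anew for each. This p therefore cannot test the difference in response by itself. A biological difference in response stays open.

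The second pattern is the fall of the shade avoidance list in WT at 60 min, -2.1 (95% interval -2.31 to -1.89). A signal that needs STN7 is argued against, since the genotype difference of the list mean was -0.23 with an upper limit of 0.06. An array difference between replicates and RNA integrity are argued against too, with list means of -2.21 and -2.09 under the covariates. These tables leave as a hypothesis that the change of light itself may lower IAA29, HAT2 and YUC2. That explanation was not tested, because no group stayed in PSI light.

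The third pattern is the rise of the mitochondrion-encoded list in the genotype difference of the 60 min response, 0.58 (95% interval 0.3 to 0.86; adjusted p = 0.457 with an estimated correlation). RNA integrity is argued against as the whole cause, since with the 3' to 5' covariate the mean was 0.55 (0.21 to 0.88). With the axis as a covariate it was 0.47 (0.04 to 0.91). A lower limit of 0.04, from an axis estimated on these same arrays, cannot exclude an array difference between replicates as the whole cause. Both intervals reach below 0.29, 50% of the shift, so that each may account for a part as large. A share of organelle RNA that differs between arrays would move plastid-encoded genes the same way, and their mean was -0.22 with an upper limit of 0.33, above 0.29. This share, such parts and an array difference as the whole cause stay open and cannot be told apart from a biological difference between the genotypes. The list mean lay between 5.3 and 5.8 in every array, under the array medians of 6.1 to 6.31, so background can make up part of these values. The label was primed on poly(A) tails, which represents organelle transcripts poorly, and its part in the shift was not tested.

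In the 30 min response the mitochondrial list differed by 0.56 on average (camera adjusted p = 2.83e-06; adjusted p = 0.233 with an estimated correlation). This value shares its 0 min arrays with that of the 60 min response and is no independent repeat of it. The list mean of *stn7* minus WT was -0.3 at 0 min, 0.26 at 30 min and 0.28 at 60 min, so the 0 min difference enters both responses. The genes that differed upward were CHI (2.28), AT2G07741 (1.77), cox2 (1.73), SPT (1.42), AT5G25450 (1.39), nad5 (1.37), AT5G12110 (1.37), AT1G14120 (1.33), nad1 (1.28, on a probe set not counted for the list) and AT1G36060 (1.24). AT2G07741 is a nuclear locus within a copy of mitochondrial DNA, and its probe set matches several sequences, so the origin of its signal is uncertain. The members nad6 (1.16), ccb452 (1.12), cox1 (1.09) and nad9 (1.01) differed too. The probe sets of nad6 and ccb452, and that of nad5 here, are also of a type that can match several sequences. The origin of their signal is therefore uncertain as well. The genes that differed downward were AT3G05730 (-2.31), COR15A (-2.17), 3xHMG-box2 (-2.09), AT5G01870 (-1.83), AT5G50740 (-1.82), AT1G04800 (-1.77), AT4G22000 (-1.7), AT3G13190 (-1.68), AT3G05760 (-1.65) and AT3G52220 (-1.64). Of these 20 largest differences CHI, AT2G07741, cox2, AT5G12110 and COR15A were called with every single array left out. The other 15 were not called without WT 0 min replicate 1 (adjusted p 0.0664 to 0.129) or replicate 3 (0.0597 to 0.131). Some were also not called without *stn7* 0 min replicate 1 or 2, any WT 30 min array or any *stn7* 30 min array, up to 0.135 for AT3G52220 without *stn7* 0 min replicate 1. With the axis as a covariate CHI, AT2G07741, AT5G12110, AT3G05730 and COR15A passed and the other 15 did not (adjusted p 0.0598 to 0.387). Among those cox2 went from 1.73 ± 0.26 to 1.41 ± 0.27, AT5G01870 from -1.83 ± 0.35 to -2.07 ± 0.39, and AT5G50740 from -1.82 ± 0.43 to -0.91 ± 0.28. With the 3' to 5' covariate AT1G04800, AT4G22000, AT3G13190 and AT3G52220 did not pass (adjusted p 0.0532, 0.0605, 0.0623 and 0.0585). Over all calls of this response the median size was 0.89 without and with that covariate, and the SE was 1.02 times as large. These lost calls therefore do not speak for RNA integrity as a cause.

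In the 60 min response the upward differences were THI2.1 (2.16), AT1G54020 (2.05), SPT (1.87), cox2 (1.84), SWEET16, a vacuolar sugar transporter gene (1.82), AT5G40020 (1.76), AT2G07741 (1.72), AT1G14120 (1.61), CHI (1.59) and AT4G21870 (1.55). The downward differences were AT3G29075 (-4.1), NET4B (-3.82), AT5G66060 (-3.76), AT5G16730 (-3.52), AT2G40650 (-3.52), AT2G02160 (-3.49), AT2G44760 (-3.46), AT1G64330 (-3.37), AT2G01100 (-3.36) and AT4G08310 (-3.28). AT1G54020 was not called without WT 0 min replicate 1 (adjusted p = 0.0718), WT 60 min replicate 1 (0.0554) or 3 (0.0522), *stn7* 0 min replicate 1 (0.0804) or 2 (0.0653), or *stn7* 60 min replicate 1 (0.0842). Of the fixed lists LHCB4.2 (-0.43), PSBY (-0.36), SBPASE (-0.76), PORB (-0.5), GSA1 (-0.86), HAT2 (-0.55), TAPX (-0.56) and UGT74B1 (-1.96) differed downward, and GI (0.5) and UBC21 (0.6) upward. Plastid psaB (-0.98), rps19 (-1.24) and rpl16 (-1.35) differed downward and psbH (0.78) upward. Mitochondrial nad5 (1.25), nad1 (1.24), ccb452 (1.16), nad6 (1.04), cox1 (0.87) and nad9 (0.81) differed upward.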

How the results depend on the processing

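The within-group axis, the 3' to 5' difference and the poly-A spikes as covariates, leaving out both outlying WT 0 min arrays, and the arrays left out of the list tests were chosen after the results were seen; the rest were planned. Quantile normalization, both filters on dim probe sets and the trended robust variance kept the total count of every comparison within 1.5 times its value as reported. The counts by direction were not held to this limit. The cause of the changes below was not tested, except that a fold minimum can only lower a count and that leaving out arrays leaves fewer samples.

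With the axis as a covariate the counts were 85 for WT at 30 min, 1272 at 60 min and 583 between 30 and 60 min, 1110 between 30 and 60 min in *stn7*, 3, 828 and 546 for *stn7* against WT at 0, 30 and 60 min, and 11 and 0 for the genotype difference in the 30 and 60 min responses (limma; 1948 for the last at an unadjusted p under 0.05). With the 3' to 5' covariate they were 46 for WT between 30 and 60 min, 1099, 1805 and 66 for *stn7* at 30 min, at 60 min and between them, 1151 for *stn7* against WT at 60 min, 1353 over all times and 304 for the 30 min response. In these comparisons the median size of the called changes ran from 0.29 to 0.89 both without and with that covariate, and the SE was 1.02 to 1.61 times as large. Array weights gave 680 for WT between 30 and 60 min, 2597 for *stn7* at 30 min, 772 and 4549 for *stn7* against WT at 30 and 60 min, 3558 over all times and 1500 for the 30 min response. Leaving out both outlying WT 0 min arrays gave 250 and 1937 for WT at 30 and 60 min, 3 for *stn7* against WT at 0 min, 1172 over all times, and 3 and 742 for the responses. That leaves 1 WT 0 min array, replicate 2, assumed to vary like the other groups. It had the lowest array weight, 0.53, so lower counts here do not show that the arrays left out were at fault. The 3 at 0 min, named after their values were seen, were AT1G64380 (1.2 ± 0.18) and 2 probe sets without a gene in the annotation, among them the one with the largest fall in *stn7*, against 2148 at an unadjusted p under 0.05. Fits to only the groups compared gave 798 for *stn7* at 30 min, 1 and 194 for *stn7* against WT at 0 and 30 min and 29 for the 30 min response. Median centring gave 5729 at 0 min and the poly-A spikes 910 for the 30 min response. The replicate number as a block gave 265 for *stn7* against WT at 30 min and 155 for the 30 min response. Same-numbered arrays did not pair, with a median correlation of -0.07 against 0.005 for other pairs. Replicate numbers here follow the sample titles, while the descriptions number the third 0 min sample 4 in WT and 5 in *stn7*, so the block and the pairing rest on the titles.

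A 2-fold minimum left 813, 1294 and 56 in WT, 149, 441 and 406 in *stn7*, 288, 36 and 378 for *stn7* against WT at 0, 30 and 60 min, 13 over all times and 161 and 1416 for the responses. Leaving out each array in turn gave 3997 to 6839, 5865 to 7791 and 55 to 265 in WT, 684 to 2143, 2638 to 3637 and 1551 to 3887 in *stn7*, 664 to 5039, 92 to 322 and 1265 to 3103 for *stn7* against WT, 1611 to 2776 over all times, and 18 to 2216 and 3560 to 6043 for the responses. The arrays behind the large moves are named in the results.

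Of the fixed lists 16 shifts passed as reported, 5 with an estimated correlation and 41 with fry, and 15 to 23 with each array left out. Some values reversed. The plastid-encoded mean with the axis was -0.134 for WT at 60 min (adjusted p = 0.367), -0.288 for *stn7* against WT at 0 min (4.64e-06), and 0.312 (2.05e-05) and 0.378 (2.08e-05) for the 30 and 60 min responses. These 3 did not pass with an estimated correlation (adjusted p 0.808, 0.662 and 0.608), and the 95% intervals of their means, -0.72 to 0.14, -0.22 to 0.85 and -0.31 to 1.07, include 0. For the 30 min response it was -0.162 without WT 0 min replicate 2 and 0.186 without replicate 3 (adjusted p = 0.0467; adjusted p = 0.576 with an estimated correlation). Without both outlying arrays it was -0.01 (0.926) for WT at 60 min, -0.272 (9.73e-05) for *stn7* against WT at 0 min and 0.301 (5.26e-05) for the 30 min response, none of which passed with an estimated correlation (adjusted p 0.978, 0.812 and 0.602). AT1G54020 was -0.1 (0.985) in the 60 min response with the axis. Of 771 values of named genes 641 kept their direction and side of the threshold with the axis and 124 lost their call. The 771 include values that were not called as reported, so 641 does not count calls that held. Among genes named by the rule, 10 of 10 falls in WT at 60 min passed with the axis. In the 60 min response 0 of 10 rises and 0 of 10 falls did.

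The STN7 transcript and the 6 settings foreseen for it were not run. In simulated data with changes of log2 0.5, 1 and 2, the fit recovered 53.7%, 94% and 98.5% in WT at 60 min, 6%, 73.1% and 92.4% in the 30 min response, and 10.4%, 80.6% and 100% in the 60 min response, with 6 to 14 false calls per comparison. In the simulation, differences in response of log2 0.5 were therefore seldom called with 3 arrays per group. It changed only 200 probe sets, while 5091 were called in the real 60 min response, 1416 of them at a 2-fold minimum. These figures also come from noise drawn for each probe set on its own, without the within-group axis shared by the real arrays. They are no check of calls that such an axis could make. The simulated recovery and false calls therefore need not hold for the real arrays. For dim probe sets the signal lies close to the background, which limits what can be read from them.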

Other observations

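The families here were grouped by gene symbol after the annotation was seen, and their tests were chosen then. In all, 30 families were tested in each of the 12 comparisons, 3 are given here, and none of the 30 passed with an estimated correlation (lowest adjusted p = 0.249). Of 8 measured ATG genes, ATG3 and 7 of the ATG8 group, 7 fell in WT at 30 min (mean -0.676; camera adjusted p = 0.00166; adjusted p = 0.464 with an estimated correlation) and 7 at 60 min (mean -0.797, or -0.918 relative to the median shift; camera adjusted p = 0.00173; adjusted p = 0.578 with an estimated correlation). ATG8E (-1.73) and ATG8B (-1.09) were among them at 60 min. In *stn7* 4 fell at 30 min (mean -0.452; camera adjusted p = 0.00483; adjusted p = 0.705 with an estimated correlation) and 5 at 60 min (mean -0.515; camera adjusted p = 0.0057; adjusted p = 0.624 with an estimated correlation). With the within-group axis as a covariate the means were -0.317 and -0.437 in WT, with 0 genes past the threshold in limma, and -0.358 and -0.652 in *stn7*, with 3 and 5.

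Of 9 measured XTH genes, whose enzymes remodel xyloglucan in cell walls, 5 rose in *stn7* at 60 min relative to 0 min (6 when adjusted over the list alone), with XTH33 (1.26), XTH16 (1.17) and XTH18 (0.94) the largest. Their mean was 0.521 (camera adjusted p = 0.0217; adjusted p = 0.624 with an estimated correlation) and 0.413 with the axis as a covariate, with 5 past the threshold. In WT at 60 min the mean was 0.141 (camera adjusted p = 0.79) and 0.426 with the axis (camera adjusted p = 0.175). The genotype difference in the 60 min response of these genes was 0.38 (camera adjusted p = 0.166) and -0.012 with the axis (camera adjusted p = 0.869). The 3' to 5' difference was 1.39 ± 0.16 in *stn7* at 60 min against 1.18 ± 0.07 at 0 min, and with it as a covariate the *stn7* mean was 0.537, with 4 past the threshold (camera adjusted p = 0.0525).

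The 10 measured NET genes, whose proteins bind actin, had the largest mean of a family, -1.246 in the genotype difference of the 60 min response, or -1.12 relative to the median shift (6 lower, and 7 when adjusted over the list alone; camera adjusted p = 0.00146; adjusted p = 0.558 with an estimated correlation). In WT at 60 min their mean was 0.85, or 0.729 relative to the median shift, with 6 past the threshold upward and 1 downward (camera adjusted p = 0.0139; adjusted p = 0.578 with an estimated correlation). With the axis these means were -0.288 and 0.155, with 0 genes past the threshold in limma.

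The 12 nuclear photosynthesis genes of the fixed lists were also pooled after the annotation was seen. Of these 6 fell in *stn7* at 60 min (8 when adjusted over the list alone; mean -0.326; camera adjusted p = 2.42e-05; adjusted p = 0.346 with an estimated correlation). With the 3' to 5' covariate the mean was -0.32, with 3 past the threshold (camera adjusted p = 7.79e-05). In the genotype difference of the 60 min response 3 were lower (3 over the list alone; mean -0.273, or -0.147 relative to the median shift; camera adjusted p = 0.0124; adjusted p = 0.927 with an estimated correlation). Among probe sets with no gene in the annotation, the one with the largest fall in WT at 60 min, chosen after its values were seen, changed by -4.06 ± 0.33 on the log2 scale there and by -3.37 in *stn7*.

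The score on the within-group axis was related to 5 technical measures over the 18 arrays, with exact permutations within groups (46656 arrangements). The poly-A spikes gave r = 0.69 (p = 0.0174, adjusted p = 0.087) and rho = 0.59 (p = 0.0314), and r = 0.57 without the 2 arrays farthest from the median of the spikes. The 3' to 5' difference gave r = -0.1 (p = 0.768) and rho = 0.01 (p = 0.967). None of the 5 passed after adjustment.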
